A study of Danio rerio with 73 samples.

How the data were processed

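Genomic DNA from mature testes and ovaries was bisulfite-converted, amplified with multiplexed primers and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The authors deposited 1 table per fish, 73 in all, that lists for each CpG its chromosome, position and strand with the counts of methylated and unmethylated reads. These deposited counts are whole numbers and are not normalized. Per the submitters' processing notes, the tools were Trim Galore 0.4.5, FastQC 0.11.6, Bowtie2 and Bismark 16.0, and the genome build was GRCz10. Only CpG sites were listed. Any removal of PCR duplicates, and the primer sequences, are not given in the sources used here. Amplicon reads carry no molecular identifiers, so the depth overstates the number of molecules and the fish was taken as the unit of replication.

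Groups were formed from the tissue, the treatment and the title prefix in the labels. The treatments HT and LT were read as 36 °C and 28 °C from the series design. The prefixes 128 and 204 are not defined by the labels and were used as strata. All coordinates are 1-based on GRCz10. Gene annotation of that build was not used here, since the gene table at hand is of another assembly. The amplicons therefore could not be given gene names, and the gene lists fixed beforehand (testis pathway, ovary pathway, germ cell, DNA and histone modification, heat and stress, immune) could not be applied: 0 of their genes were matched to an amplicon.

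The methylation level of a CpG in a fish was the percent of methylated among all reads, with a minimum of 10 reads. CpGs with that depth in at least 50% of all fish were kept, which left 324 of 25217 listed CpGs. Kept CpGs up to 200 bp apart were joined into amplicons of at least 2 CpGs, and 323 CpGs fell into 20 amplicons. The level of an amplicon in a fish was the mean of its CpG levels where at least 50% of its kept CpGs had a level. Amplicons were called low below a mean of 5% and high above 90%, bounds set after the levels were seen. No kept CpG had a kept partner on the other strand, and 0 pairs of libraries held identical counts. Calls outside the amplicons were 0.510% of all calls. Mitochondrial CpGs, where little methylation is usually found, gave 9 methylated of 155 calls, 5.81% (95% Wilson interval 3.08 to 10.7, covering counting error only).

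The comparisons were testis against ovary at 28 °C, 36 °C against 28 °C in testis and in ovary, and testis against ovary at 36 °C. Each used a two-sided permutation test of the difference between mean levels per fish, with labels permuted within title prefix where both prefixes took part. It used 100000 resamples, or every split (exact) where a side had fewer than 10 fish and at most 3000000 splits existed. The smallest p that the resamples can give is 1e-05. At least 5 fish per side were required, and p-values were adjusted by Benjamini-Hochberg within a comparison at 0.05. Differences are stratified by prefix, so they need not equal the difference of the printed group means. The panel value is the mean over amplicons of a fish's level after each amplicon's mean over all fish was subtracted. Interactions were tested by permuting residuals under the additive model with at least 3 fish per cell. Each comparison names the amplicons past the threshold, at most 10 by size of the difference, and the 5 CpGs with the largest difference past it. The other amplicons past the threshold are named as well, and those named in ovary, where 0 passed, were chosen after their values were seen. The tests and filters of these comparisons and interactions, their alternatives except those named below, and the naming rule were fixed before the data were examined. The scale from ovary to testis, the Fisher test, the comparisons of reads outside the amplicons, the mitochondrial check, the counts of fish on the side of a difference and the number of resamples for left-out fish were set afterwards.

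The tests were tested on simulated data built from the real levels with known changes, and the simulation was revised when its changes proved too few to measure recovery. For testis against ovary at 28 °C, 75% of CpGs changed by 10 points and 95% of those changed by 20 points were recovered. The whole simulation gave 1 false call. Apart from the known changes, both sides were simulated with the mean and spread of the second group, here the ovaries. Real testes spread more widely (SD 29.2 against 9.13 at chr18:39655137), so these shares may be too high. In the simulations for temperature, the second group was the fish at 28 °C. In each simulation, CpGs of higher level were changed downward and those of lower level upward, and CpGs with a mean level of 10% or less were not changed. Alternatives were coverage minimums of 5, 30 and 100 reads, CpGs covered in 80% of fish, gaps of 500 bp, pooled counts, both strands added, the prefix ignored or each prefix alone, pairing by fish number, shallow fish left out, each fish left out in turn (20000 resamples), a quasi-binomial logistic model and limma on log2 ratios with a pseudocount of 1. Leaving out each fish in turn was planned for the amplicons, and was added after the data were seen for the panel values, the interactions and the levels outside the amplicons. The scale from ovary to testis weighted each amplicon by its difference between the reference groups and needed at least 3 amplicons per fish. The labels do not say that fish numbers pair the fish across temperatures, and the pairing check is given with the alternatives. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.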

Results

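DNA methylation was measured in the mature gonads of 73 laboratory zebrafish of the AB strain at 90 days of age. The fish had been reared at 28 °C or at 36 °C while their gonads formed, and the question was whether the early heat left differences in adult testis and ovary. The assay was multiplex bisulfite sequencing. Bisulfite turns unmethylated cytosine into a base read as T and leaves methylated cytosine as C, and PCR then amplifies chosen stretches of DNA, here in the promoter regions of 18 genes according to the series design. Libraries labelled testis numbered 43 and libraries labelled ovary 30. Sample titles carried a prefix, 128 or 204, which the labels do not define. Testes at 28 °C came from 13 fish with prefix 128 and 10 with prefix 204, and testes at 36 °C from 12 and 8 fish. Ovaries at 28 °C came from 9 fish with each prefix, and ovaries at 36 °C from 12 fish, each with prefix 204. The labels do not say whether the fish came from separate tanks or families, so the p-values measure the spread between these fish.

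Sequencing was deep and fell on few places. Each fish had between 711295 and 12565602 CpG read calls, except fish 14 of the 36 °C ovaries, which had 1404. A CpG is a cytosine followed by a guanine, and 323 CpGs formed 20 amplicons on the GRCz10 genome build. Gene annotation of that build was not used here, so each amplicon is called by its chromosome and the position of its first CpG. In 17 amplicons the median depth was at least 500 reads per CpG and fish. The others were shallow, with a median of 41 reads at chr22:20736688, 322 at chr25:22224443 and 31 at the amplicon from 6205 to 6328 on an unplaced scaffold. Of all calls, chr22:20736688 held 0.00394% and the unplaced scaffold 0.00359%. The series design names 18 genes, fewer than the 20 amplicons, and whether each amplicon was a chosen target was not determined. Averaged over all fish, 8 amplicons had a methylation level below 5%, 3 had a level above 90%, and 9 lay between.

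Testis and ovary at 28 °C differed at 12 of 20 amplicons, and 11 of these were more methylated in libraries labelled testis. The largest difference was at chr18:39655137 on chromosome 18, which ends at 39655521 and holds 15 CpGs. Its level was 68.7% ± 29.2 (SD, n = 21) in testis and 31.5% ± 9.13 (SD, n = 17) in ovary. The difference within prefixes was 33.4 points (SE 6.25), with testis above the ovary mean of the same prefix in 19 of 21 fish (permutation test, Benjamini-Hochberg adjusted p = 0.0002). The ovaries ranged from 18.5% to 52.0%. Testes with prefix 204 (25.1% to 49.1%) and fish 20 and 22 with prefix 128 (41.4% and 40.4%) lay within that range. Differences of 24.9 points (SE 4.94) at chr3:17897376 and 24.5 points (SE 7.06) at chr7:34854540 followed. The amplicon chr5:44344567, which ends at 44344999 and holds 24 CpGs, went the other way. It had a level of 13.9% ± 11.8 (SD, n = 23) in testis and 28.7% ± 7.75 (SD, n = 13) in ovary, a stratified difference of -15.9 points (SE 3.41). Testis lay below the ovary mean of the same prefix in 19 of 23 fish (permutation test, Benjamini-Hochberg adjusted p = 0.00048). With prefix 204 the ranges overlapped, at 9.35% to 34.7% in testes and 21.1% to 35.4% in ovaries (n = 4).

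The remaining amplicons that were higher in testis at 28 °C covered a wide range of levels. The stratified difference was 24.3 points (SE 10.2) at chr22:20736688, 24.0 points (SE 6.89) at the unplaced scaffold and 11.4 points (SE 3.08) at chr16:54645605. It was 10.6 points at both chr25:22224443 (SE 3.34) and chr19:27434975 (SE 2.28). The 3 amplicons of high level rose by less, with 5.93 points (SE 1.21) at chr20:1252974, 2.74 points (SE 0.707) at chr14:23501841 and 2.58 points (SE 0.807) at chr8:29856084. Of the 8 amplicons of low level, 0 passed the test. The call at chr22:20736688 was lost when any of 8 single fish was left out, for example with an adjusted p of 0.0713 without fish 12 of the ovaries with prefix 128.

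At single CpGs, 102 of 323 differed between testis and ovary at 28 °C, 77 higher and 25 lower in testis. At chr18:39655137 all 15 CpGs were higher in testis. The CpG at position 39655202 had a level of 68.9% ± 28.3 (SD, n = 21) in testis and 29.9% ± 11.2 (SD, n = 17) in ovary, a stratified difference of 35.5 points (SE 6.32), and those at positions 39655137, 39655259 and 39655401 differed by 34.7, 34.4 and 34.2 points. Of the 25 CpGs lower in testis, 22 lay in chr5:44344567. The largest of these, at position 44344955, had 35.8% ± 32.5 (SD, n = 23) in testis and 75.1% ± 6.55 (SD, n = 13) in ovary. Over the whole panel, testis lay 7.48 points above ovary (SE 1.5, permutation p = 4e-05, not adjusted).

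The difference between testis and ovary at 28 °C was present with prefix 128 and was not detected with prefix 204. With prefix 128 (n = 13 and 9), 12 of 20 amplicons and 113 of 319 CpGs passed, and chr18:39655137 stood at 87.1% ± 20.5 (SD, n = 13) in testis and 30.5% ± 12.1 (SD, n = 8) in ovary. With prefix 204 (n = 10 and 9), the exact permutation test with Benjamini-Hochberg adjustment passed 0 of 18 amplicons and 0 of 294 CpGs, and at an unadjusted p below 0.05 it gave 0 amplicons and 22 CpGs. There the level of chr18:39655137 was 38.7% ± 7.75 (SD, n = 8) in testis and 32.4% ± 6.13 (SD, n = 9) in ovary. At chr7:34854540 it was 20.1% ± 7.94 in testis and 23.6% ± 5.56 in ovary (SD, n = 9 each). The panel difference was 13.3 points (SE 1.92) with prefix 128 and 0.910 points (SE 0.979) with prefix 204. Whether the prefixes differed in this comparison was not itself tested.

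**Figure D1:**
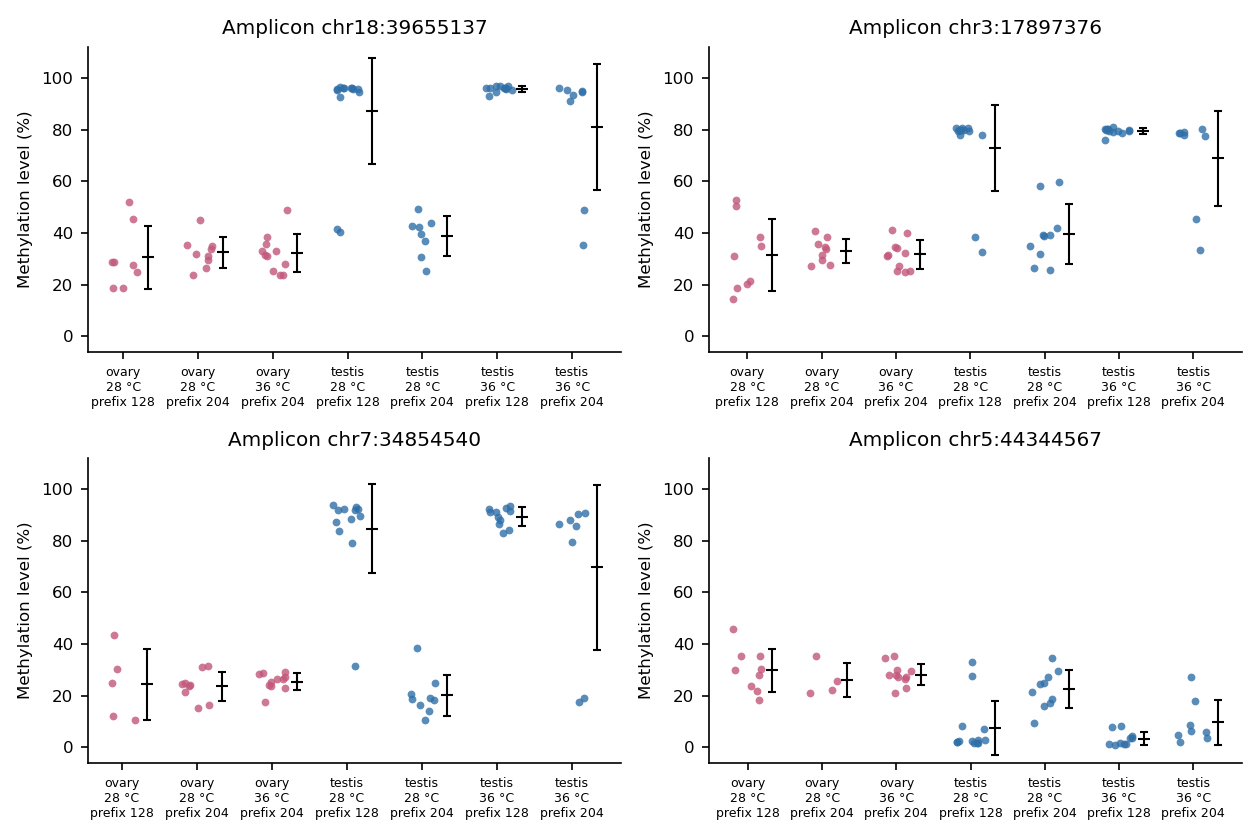
Methylation level in percent (vertical axis) of 4 amplicons in each of the 7 groups (horizontal axis). Each point is a fish, red for ovary and blue for testis, and the bars are mean ± SD. At chr18:39655137 the testes at 28 °C with prefix 204 lie between 25.1% and 49.1% and the ovaries between 18.5% and 52.0%, while the testes at 36 °C with prefix 128 lie between 92.9% and 97.0%.

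Libraries labelled testis fell into separate ranges. To describe this, each fish was placed on a scale from its levels at 11 amplicons of intermediate or high level, where 0 is the mean of the 28 °C ovaries and 100 the mean of the 36 °C testes, both with prefix 128. This scale was chosen after the levels had been seen. On it, 29 of 29 placed ovaries lay below 50, while 14 of 43 libraries labelled testis lay below 50 and 29 above. No fish lay between 41.8 and 67.1. The 14 libraries were 10 of 10 testes at 28 °C with prefix 204, 2 of 8 testes at 36 °C with prefix 204 (fish 1 and 17) and 2 of 13 testes at 28 °C with prefix 128 (fish 20 and 22). The testes at 28 °C with prefix 204 had a mean position of 6.35 ± 15.9 (SD, n = 10) and the ovaries of the same prefix and temperature -1.08 ± 7.52 (SD, n = 9). This difference, 7.44 (SE 5.81), did not exceed the spread between fish (exact permutation p = 0.233, two-sided).

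**Figure D2:**
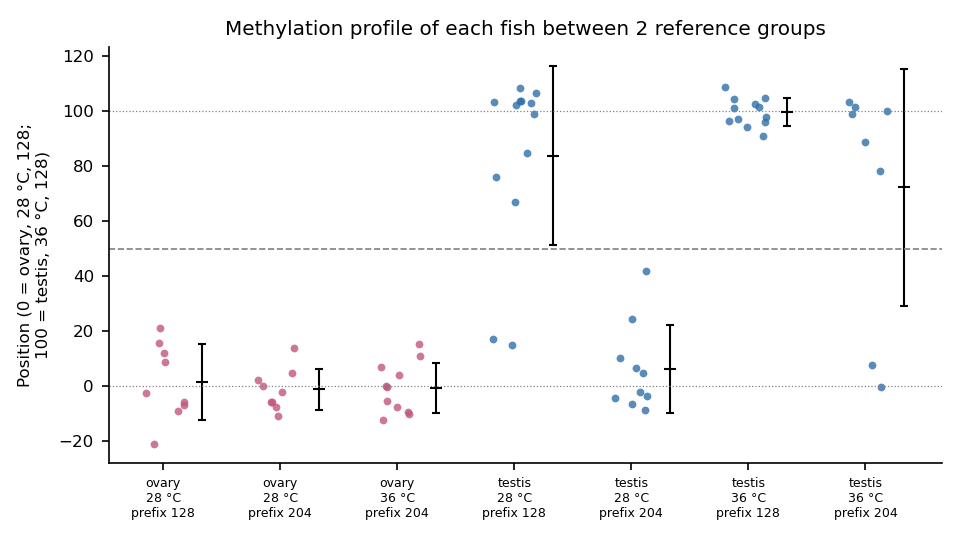
Position of each fish (points, red for ovary and blue for testis) on a scale from 0, the mean of the 28 °C ovaries with prefix 128, to 100, the mean of the 36 °C testes with prefix 128 (vertical axis, no unit), in the 7 groups, with mean ± SD. The dashed line marks 50, and no fish lies between 41.8 and 67.1.

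Rearing at 36 °C went with higher methylation at 10 and lower methylation at 1 of 20 amplicons in libraries labelled testis. At chr18:39655137 the level was 90.0% ± 16.6 (SD, n = 20) at 36 °C and 68.7% ± 29.2 (SD, n = 21) at 28 °C, a stratified difference of 21.9 points (SE 5.66). It lay above the 28 °C mean of the same prefix in 19 of 20 fish (permutation test, Benjamini-Hochberg adjusted p = 0.0026). With prefix 128 that mean was lowered by fish 20 and 22 (41.4% and 40.4%), and the other 11 of 13 fish at 28 °C lay above it as well. The unplaced scaffold, without a level in fish 1 and 17 of the 36 °C testes with prefix 204, rose by 24.3 points (SE 5.84), chr7:34854540 by 23.8 points (SE 6.56) and chr3:17897376 by 16.0 points (SE 4.40). At chr25:22224443, where only prefix 204 had levels at both temperatures, the rise was 23.8 points (SE 5.0). There 7 of 7 fish at 36 °C lay above the mean of the 8 at 28 °C (exact permutation test, Benjamini-Hochberg adjusted p = 0.0026). Of these 7, fish 1 (45.2%) and fish 17 (45.7%) lay within the 28 °C range, 37.7% to 46.0%. The amplicon chr5:44344567 was lower at 36 °C, with 6.13% ± 6.66 (SD, n = 18) against 13.9% ± 11.8 (SD, n = 23).

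Smaller rises in libraries labelled testis were 9.53 points (SE 2.62) at chr16:54645605, 6.48 points (SE 2.23) at chr19:27434975 and 3.74 points (SE 1.17) at chr20:1252974. They were 2.69 points (SE 0.799) at chr8:29856084 and 1.49 points (SE 0.602) at chr14:23501841. The last of these calls was lost without any of 8 single fish, each with prefix 204, for example with an adjusted p of 0.0585 without fish 7 of the 28 °C testes. At single CpGs, 92 of 323 differed, 81 higher and 11 lower at 36 °C, and 10 of the 11 lay in chr5:44344567. Among the 5 CpGs with the largest difference, 4 lay in the shallow amplicon chr22:20736688. The CpG at position 20736744 had 74.5% ± 35.8 (SD, n = 11) at 36 °C and 38.2% ± 36.2 (SD, n = 16) at 28 °C. Another lay at position 22224496 on chromosome 25, with 54.4% ± 20.4 (SD, n = 7) at 36 °C and 20.4% ± 4.23 (SD, n = 8) at 28 °C. The panel difference was 6.12 points (SE 1.55, permutation p = 0.00033, not adjusted). With the prefix ignored, 4 CpGs passed in place of 92.

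The temperature difference in libraries labelled testis was carried by prefix 204. With that prefix (n = 8 and 10), 13 of 19 amplicons and 100 of 318 CpGs passed, and chr7:34854540 stood at 69.7% ± 31.8 (SD, n = 8) at 36 °C and 20.1% ± 7.94 (SD, n = 9) at 28 °C. With prefix 128 (n = 12 and 13), the permutation test with Benjamini-Hochberg adjustment passed 0 of 19 amplicons and 0 of 312 CpGs, with 3 amplicons and 19 CpGs at an unadjusted p below 0.05. The level of chr7:34854540 there was 89.3% ± 3.54 (SD, n = 11) at 36 °C and 84.5% ± 17.2 (SD, n = 12) at 28 °C. The interaction of temperature and prefix was itself tested and passed at 12 of 19 amplicons, each with a rise in prefix 204 above the change in prefix 128 (residual permutation, Benjamini-Hochberg). In simulated data for prefix 128, 3 of 16 CpGs (18.8%) changed by 10 points and 10 of 18 (55.6%) changed by 20 points were recovered. Both sides had the spread of the 28 °C testes, an SD of 20.5 at chr18:39655137, where the real 36 °C testes had 1.14. Highly methylated CpGs were changed downward only, so recovery of rises from high levels was not measured.

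**Figure D3:**
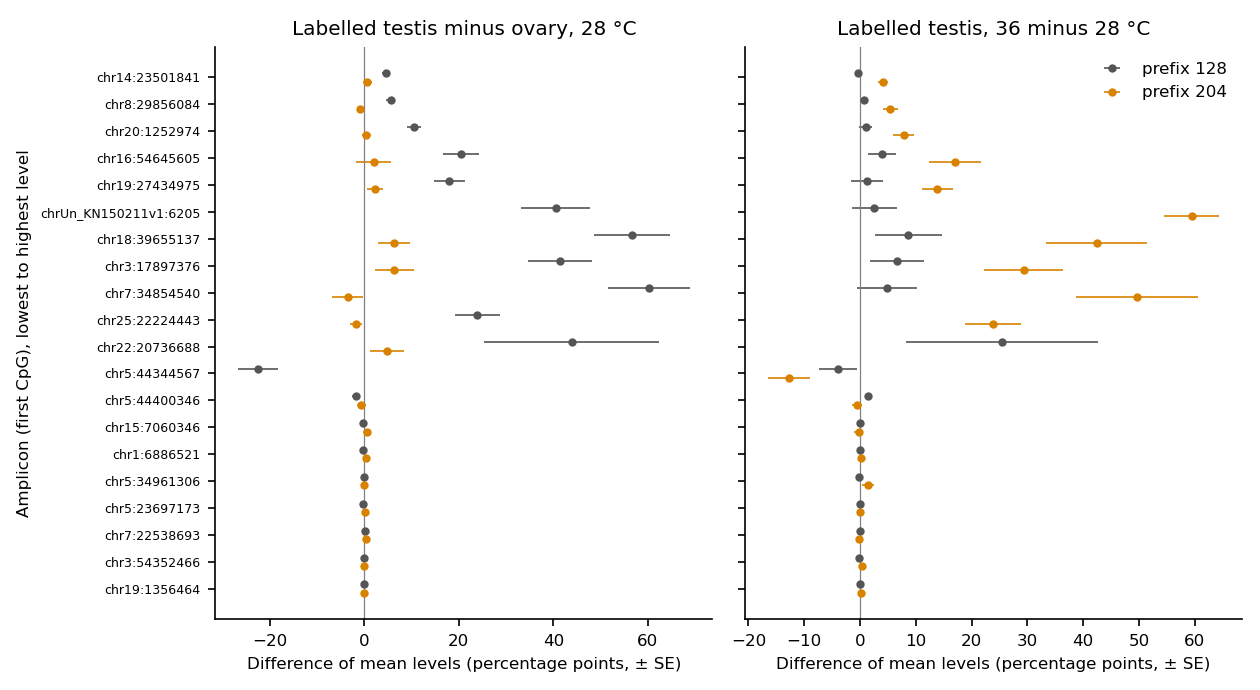
Difference of mean methylation level in percentage points ± SE (horizontal axis) at each amplicon (vertical axis), with prefix 128 in grey and prefix 204 in orange. The left panel gives labelled testis minus ovary at 28 °C and the right panel labelled testis at 36 °C minus 28 °C. At chr7:34854540 the left difference is 60.2 points with prefix 128 and -3.54 points with prefix 204, and the right one is 4.82 and 49.6 points.

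In ovary, 0 of 18 amplicons and 0 of 294 CpGs differed between rearing temperatures (12 and 9 fish, prefix 204, exact permutation test with Benjamini-Hochberg adjustment). At an unadjusted p below 0.05 there were 5 amplicons and 20 CpGs. The limma model also gave 0 of each, and the quasi-binomial logistic model gave 1 amplicon and 4 CpGs. The level of chr18:39655137 was 32.1% ± 7.39 (SD, n = 11) at 36 °C and 32.4% ± 6.13 (SD, n = 9) at 28 °C, and that of chr3:17897376 was 31.7% ± 5.70 (SD, n = 11) and 33.2% ± 4.67 (SD, n = 9). The largest difference in size was 5.04 points (SE 3.26) at chr16:54645605. The smallest p was at chr19:1356464, with 0.181 points (SE 0.0620, exact permutation test, adjusted p = 0.112), which passed without fish 3 of the 36 °C ovaries (adjusted p = 0.0346). The other 4 amplicons below 0.05 before adjustment differed by 0.234 points (SE 0.104) at chr5:23697173, 1.27 points (SE 0.605) at chr8:29856084, 0.419 points (SE 0.281) at chr5:34961306 and 1.39 points (SE 0.673) at chr14:23501841 (adjusted p = 0.176 for each). At chr5:34961306 fish 14 of the 36 °C ovaries, with 1404 read calls, stood at 3.40%, and the next highest of that group at 1.01%. The difference there rests in part on that fish. The panel difference was 1.61 points (SE 1.20, exact permutation p = 0.205, not adjusted), and 0.855 points (SE 0.867, p = 0.335) without fish 14 of the 36 °C ovaries, which had a level at 1 amplicon. Its p fell below 0.05, not adjusted, with a minimum of 30 reads, at 1.19 points (exact permutation p = 0.0407), with 100 reads and with CpGs covered in 80% of fish. In simulated data for this comparison, 11 of 14 CpGs (78.6%) changed by 10 points and 17 of 17 (100%) changed by 20 points were recovered. Smaller changes, such as the amplicon differences seen here, were not simulated. CpGs with a mean level of 10% or less were not changed, so recovery there was not measured. Amplicon chr5:44344567 and the unplaced scaffold could not be tested, since only 4 ovaries at 28 °C with prefix 204 had a level there.

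After rearing at 36 °C, testis and ovary differed at 14 of 19 amplicons, 13 higher and 1 lower in testis (8 and 12 fish, prefix 204). The unplaced scaffold had a level of 96.2% ± 2.59 (SD, n = 6) in testis and 43.3% ± 16.1 (SD, n = 8) in ovary, a difference of 52.8 points (SE 6.7) seen in 6 of 6 testes (exact permutation test, Benjamini-Hochberg adjusted p = 0.00105). The 2 testes without a level there, fish 1 and 17, were the 2 of this group below 50 on the scale, so this size does not compare with amplicons that include them. At chr18:39655137 the level was 81.2% ± 24.4 (SD, n = 8) in testis and 32.1% ± 7.39 (SD, n = 11) in ovary, and 8 of 8 testes lay above the ovary mean (exact permutation test, Benjamini-Hochberg adjusted p = 0.00044). Fish 1 (35.5%) and fish 17 (48.7%) of these testes lay within the range of the ovaries, 23.6% to 48.9%. Differences of 44.3 points (SE 9.56, in 6 of 8 testes) at chr7:34854540 and 37.2 points (SE 5.89, in 8 of 8) at chr3:17897376 followed. At chr3:17897376 testis fish 1, at 33.3%, lay within the ovary range, 24.9% to 41.3%. At chr5:44344567, 8 of 8 testes lay below the ovary mean, with 9.59% ± 8.61 (SD, n = 8) against 28.2% ± 4.25 (SD, n = 11). Testis fish 17, at 27.32%, lay within the ovary range there, 20.97% to 35.30%.

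Other amplicons higher in testis after 36 °C differed by 18.6 points (SE 4.56) at chr25:22224443, 16.0 points (SE 2.67) at chr19:27434975 and 14 points (SE 4.16) at chr16:54645605. The 3 amplicons of high level differed by 7.12 points (SE 1.73) at chr20:1252974, 3.40 points (SE 0.722) at chr14:23501841 and 3.27 points (SE 1.17) at chr8:29856084. Of the low-level amplicons 3 of 8 passed, with differences of 0.470 points at chr1:6886521, 0.249 points at chr7:22538693 and 0.246 points at chr3:54352466. Without fish 11 of these testes the first difference was 0.204 points and still passed (exact permutation test, adjusted p = 0.0410). The calls at chr7:22538693 and chr3:54352466 rested on single fish. The first was lost without any of 10 fish and the second without any of 13, with 0.0590 and 0.130 points left without fish 11 (exact permutation test, adjusted p = 0.151 and 0.156). Without it, chr15:7060346 and chr5:23697173 passed as lower in testis, by -0.319 and -0.253 points. At single CpGs, 108 of 318 differed, 85 higher and 23 lower in testis, and 22 of the 23 lay in chr5:44344567. The 5 CpGs with the largest difference were the 5 of the unplaced scaffold, where fish 1 and 17 had no level. At position 6205 testis had 95.8% ± 5.65 (SD, n = 6) and ovary 37.9% ± 18.0 (SD, n = 7). The panel difference was 11.3 points (SE 2.36, exact permutation p = 0.000341, not adjusted).

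**Figure D4:**
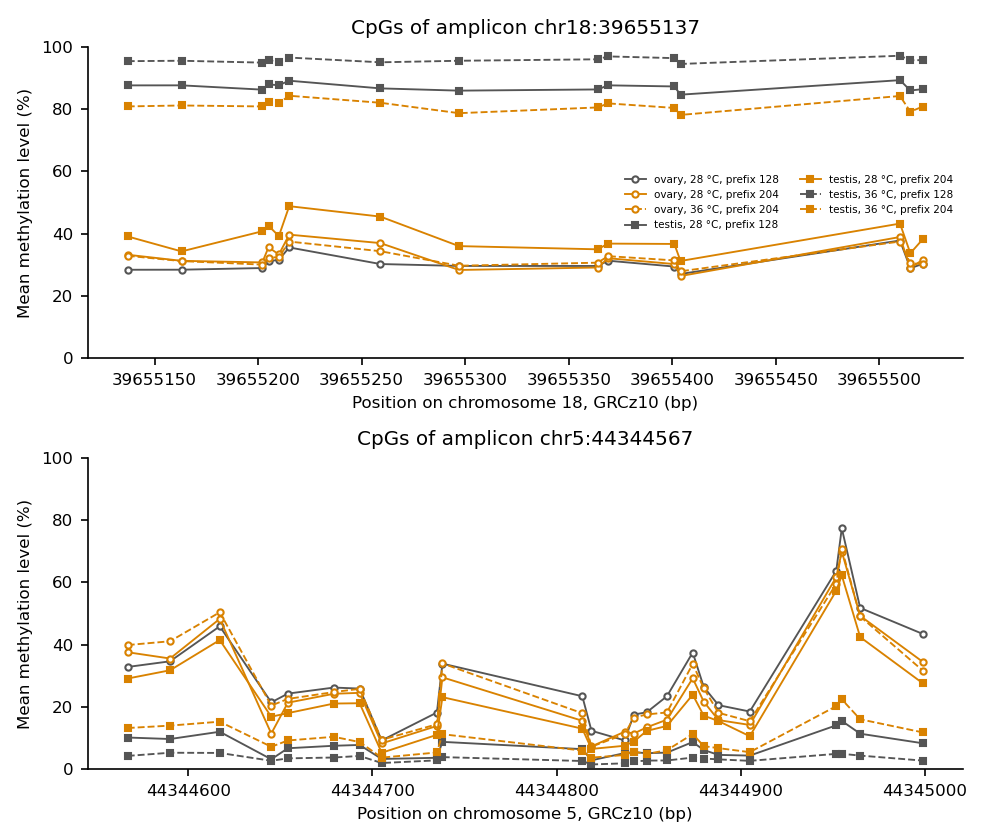
Mean methylation level in percent (vertical axis) of each CpG along amplicons chr18:39655137 and chr5:44344567 (horizontal axis, position in bp on GRCz10), 1 line per group, with squares for testis, circles for ovary and dashed lines for 36 °C. At chr18:39655137 the 28 °C testes with prefix 204 (orange squares, solid line) run near the ovaries, with an amplicon mean of 38.7% against 32.4% in the ovaries of the same prefix and temperature.

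Whether the temperature difference itself differed between testis and ovary could be tested with prefix 204, which held all 4 groups. It did at 11 of 20 amplicons, 10 with a rise in testis above the change in ovary and 1, chr5:44344567, with a fall in testis and no fall in ovary (28.2% at 36 °C, n = 11, and 26.1% at 28 °C, n = 4; residual permutation, Benjamini-Hochberg). The difference between the temperature effects was 47.8 points (SE 10.3) at chr7:34854540 and 42.8 points (SE 8.77) at chr18:39655137. It was 55.6 points (SE 10.7) at the unplaced scaffold, where fish 1 and 17 of the 36 °C testes had no level and only 4 ovaries at 28 °C had one. All 10 libraries at 28 °C on the testis side of this test lay below 50 on the scale from ovary to testis.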

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

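All tests of explanations here, the scale from ovary to testis, the Fisher test and the comparisons of reads outside the amplicons were chosen after the results had been seen. The splits of the fish were planned, but their bounds were written down after the counts were known.

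A first pattern is the set of 14 libraries labelled testis that lay below 50 on the scale. Of these, fish 2 and 7 of the 28 °C testes with prefix 204, at 24.5 and 41.8, lay above the highest ovary at 21.3. An exchange of labels between testis and ovary libraries would leave ovary labels above 50, and 0 of 29 placed ovaries were there. The 9 ovaries at 28 °C with prefix 128 define the scale's 0, so their place is partly fixed. Of the ovaries with prefix 204, which do not define it, 11 of 11 at 36 °C and 9 of 9 at 28 °C lay below 50. A mixture with at least 50% testis-type DNA would put the 28 °C testes with prefix 204 near 50 on the scale, and their mean was 6.35 (SE 5.01). This mean includes fish 7 at 41.8, which was placed from 5 amplicons. A smaller share of testis-type DNA, or a mixture in single libraries such as fish 2 and 7, was not tested and stays open. The 28 °C testes with prefix 204 may also hold ovary DNA under a wrong tissue label, or gonads called testis may carry ovary-type methylation. The position of these libraries differed from the ovaries by 7.44 (SE 5.81). A wrong label and such a gonad cannot be told apart, because the levels alone do not record the tissue. The share above 50 was 6 of 8 at 36 °C and 0 of 10 at 28 °C with prefix 204 (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00302). With prefix 128 it was 11 of 13 at 28 °C, and the test there is not used, since the 36 °C testes define the scale's upper end. The share does not tell a wrong label from a gonad type, so an effect of rearing temperature on gonad type stays open, as does any difference between the prefixes.

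A second pattern is the temperature difference in libraries labelled testis. Its profile over 19 amplicons with prefix 204 followed that of testis against ovary with prefix 128, which shares no libraries with it (Pearson r = 0.946, Spearman rho = 0.940, permutation p = 1e-05 for each, the smallest possible, and r = 0.926 without the 2 farthest amplicons). Amplicons are not independent replicates. The permutation treats them as exchangeable, although those of low level changed little in both comparisons. The correlation and its p may therefore partly reflect how far each amplicon's level could change. Whether wrong tissue labels, gonad type or an effect of temperature within testes lies behind the difference stays open, since 0 of 10 testes at 28 °C with prefix 204 lay above 50.

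The third pattern is fish 11 of the 36 °C testes with prefix 204, which stood apart from its group at 4 low-level amplicons. Its levels were 2.88% at chr1:6886521, 4.42% at chr15:7060346, 10.2% at chr5:34961306 and 2.0% at chr7:22538693, where the other fish reached at most 1.48%, 1.06%, 0.987% and 0.675%. Uniform incomplete bisulfite conversion could raise low levels, but the excess should then be alike between amplicons. It ranged over 11.7 points among 7 low amplicons, from 9.66 at chr5:34961306 to -2.02 at chr5:44400346, against a largest SD of 1.84 between the other fish. No biological explanation was tested.

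Outliers were looked for in 89 sets of 4 to 10 fish, each set being 1 amplicon in 1 group, and 15 were found. The rule flags about 1 in 20 sets when levels are normally distributed. Many of these levels lie near the lower limit or fall into separate ranges, so the number that chance gives is not known. Besides fish 11, the 28 °C testes with prefix 204 had fish 2 at 3.78% for chr1:6886521 and 98.1% for chr14:23501841, and fish 7 at 7.56% for chr15:7060346 and 3.94% for chr7:22538693. Ovaries at 28 °C had fish 9 (prefix 128) at 3.77% for chr1:6886521, fish 14 (prefix 128) at 2.07% for chr5:34961306, fish 20 (prefix 204) at 1.62% for chr15:7060346 and fish 13 (prefix 204) at 77.1% for chr16:54645605. Fish 4 of the 36 °C ovaries had 19.1% at chr22:20736688. Fish 1 of the 36 °C testes with prefix 204 had 87.1% at chr8:29856084, and fish 22 of the 28 °C testes with prefix 128 had 56.0% at the unplaced scaffold. These last 2 fish are among the 14 below 50 on the scale.

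The temperature difference (36 °C minus 28 °C) was higher in testis than in ovary, with prefix 204, by 2.74 points at chr14:23501841, 42.8 at chr18:39655137, 13.7 at chr19:27434975, 6.66 at chr20:1252974 and 20.3 at chr25:22224443. It was higher by 30.8 points at chr3:17897376, 0.319 at chr3:54352466, 47.8 at chr7:34854540, 4.15 at chr8:29856084 and 55.6 at the unplaced scaffold, and differed by -14.9 points at chr5:44344567. The call at chr14:23501841 was lost without any of 18 single fish, and that at chr3:54352466 without fish 11 of the 36 °C testes, where 0.203 points were left (adjusted p = 0.0773). Between prefixes, the temperature difference in testis was higher with prefix 204 by 4.54 points at chr14:23501841, 13.1 at chr16:54645605, 33.8 at chr18:39655137, 0.227 at chr19:1356464, 12.6 at chr19:27434975 and 6.80 at chr20:1252974. It was higher by 22.7 points at chr3:17897376, 0.466 at chr3:54352466, 1.59 at chr5:34961306, 44.8 at chr7:34854540, 4.75 at chr8:29856084 and 56.9 at the unplaced scaffold. Both scaffold values lack fish 1 and 17 of the 36 °C testes with prefix 204, which had no level there. Without fish 11 of the 36 °C testes with prefix 204 the value at chr5:34961306 was 0.390 (adjusted p = 0.00285), and without fish 13 of that group the call at chr19:1356464 was lost (adjusted p = 0.0511).

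Reads outside the amplicons also gave a signal, with 348 CpGs covered by at least 10 reads in at least 10 fish. The mean level per fish, over each CpG outside the amplicons with at least 10 reads in that fish, was 47.4% ± 18.9 (SD, n = 9) in the 28 °C testes with prefix 204 and 63.2% ± 7.95 (SD, n = 13) in those with prefix 128, a difference of -15.8 points (SE 5.84, exact permutation test, Benjamini-Hochberg adjusted p = 0.0178). The call rested on fish 3 of the former, at 3.01% from 37 CpGs. Without it the difference was -10.2 points and did not pass (adjusted p = 0.0676). The other 3 comparisons made did not pass (exact permutation tests): testis against ovary at 28 °C with prefix 128 (adjusted p = 0.886) and with prefix 204 (0.173), and at 36 °C with prefix 204 (0.188). The CpGs covered differed between fish.

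Chance was weighed with 100 splits of the same fish into groups of the same sizes within strata, the labelled split included. The labelled split of testis and ovary at 28 °C gave 12 amplicons and 99 CpGs at 5000 resamples, and the highest other split 6 and 30, so 1 of 100 splits was as large for each. For temperature in testis it gave 11 amplicons, against 12 in the highest other (2 of 100 as large), and 92 CpGs against 46 (1 of 100). For testis and ovary at 36 °C it gave 14 amplicons against 11 and 107 CpGs against 93 (1 of 100 each). The interactions gave 11 amplicons against 5 by tissue and 12 against 9 by prefix (1 of 100 each). Splits as large were rare, so chance in the grouping alone is an unlikely account of these counts, but 100 splits cannot exclude it. This holds least for the amplicons by temperature in testis, where another split gave more. For temperature in ovary, with 0 amplicons and 0 CpGs, 100 of 100 splits are as large by construction, which says nothing on chance, and the highest others gave 3 and 4.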

How the results depend on the processing

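Leaving out each fish in turn was added after the data were seen for panel values, interactions and levels outside the amplicons, and the other alternatives were chosen before the data were examined. Of the counts and panel values that answer a comparison, 107 values under alternatives other than a single fish left out were the same in direction and side of the threshold, or within 1.5 times for counts. Under these alternatives 9 counts moved further, 3 panel values no longer passed and 3 passed newly. With a single fish left out 331 values were the same, with 1 exception given below. For counts only the totals were compared, not their split into higher and lower. At the named amplicons and CpGs, 305 values under alternatives other than a single fish left out were the same, 43 no longer passed and 2 reversed. The 43 came from prefix 128 alone (13), prefix 204 alone (12), pairing by fish number (11) and the prefix ignored (7). Testis against ovary at 28 °C gave 0 amplicons, 0 CpGs and a panel difference of 0.910 points with prefix 204 alone. There chr25:22224443, chr7:34854540 and chr8:29856084 reversed, to -1.78, -3.54 and -0.883 points. Temperature in testis gave 0 amplicons, 0 CpGs and 1.96 points with prefix 128 alone, and 4 CpGs with the prefix ignored. With prefix 128 alone chr14:23501841 reversed, to -0.400 points. Temperature in ovary gave 1 amplicon and 4 CpGs in the quasi-binomial logistic model. Its panel difference passed at minimums of 30 reads (1.19 points, exact permutation p = 0.0407) and 100 reads (1.25 points, p = 0.0340) and with CpGs covered in 80% of fish (1.71 points, p = 0.0417). The cause of these changes was not tested. Pairing by fish number gave a panel difference of 3.0 points in testis, with 0 amplicons and 0 CpGs from the 10 numbers present at both temperatures, and 0 and 0 in ovary. Only the testis pairs numbered 2, 8 and 17 of prefix 204 came from the prefix that carried the temperature difference. The other testis pairs had prefix 128, so the 0 counts do not show that pairing removes that difference. The numbers were not taken to pair the fish, since correlations of same-numbered fish ran from -0.506 to 0.607 in testis (4 of 10 above 0.1) and from -0.246 to 0.513 in ovary (3 of 6). With each fish left out in turn, amplicon counts ranged from 11 to 13 for testis against ovary at 28 °C, 12 to 15 at 36 °C, 10 to 11 for temperature in testis and 0 to 1 in ovary. The 1 was chr19:1356464 without fish 3 of the 36 °C ovaries (adjusted p = 0.0346). Interactions ranged from 9 to 13 amplicons by tissue and 11 to 13 by prefix. Panel differences ranged from 6.89 to 7.85 points for testis against ovary at 28 °C, 10.5 to 13.1 at 36 °C, 5.62 to 6.65 for temperature in testis and 0.855 to 2.0 in ovary, and the difference outside the amplicons from -18.7 to -10.2. At chr5:44400346, where testis was lower with all fish without passing, the difference passed at 28 °C without fish 3 (prefix 128) or fish 6 (prefix 204) of the ovaries, and at 36 °C without ovary fish 16 or 20 or testis fish 18 or 19. Depth limits chr22:20736688 and the unplaced scaffold, with medians of 41 and 31 reads.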
